A study of Homo sapiens with 4 samples.

How the data were processed

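Chromatin immunoprecipitation followed by sequencing was performed on 4 libraries of cells given as HepG2, an established human liver cancer cell line. The identity of the cells was not checked here. The libraries were 1 immunoprecipitate (IP) with an antibody against ASPM, 1 with an antibody against FoxM1, and 1 control library for each. The titles call both controls input, whereas their antibody label says IgG, so the kind of control is uncertain. Cross-linked cells were lysed, the protein was precipitated and the recovered DNA was made into sequencing libraries, per the labels' protocols.

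Each IP came with 1 peak list deposited by the authors, and the control libraries had no list of their own here. MACS2 2.1.1 (a peak caller), HOMER 4.10 (a peak annotator) and ChIPseeker 1.5.1 are named in the submitters' processing notes, which give neither their order nor their settings. The build is hg38, per the same notes. Each row of a deposited list held the position of a peak, its number, the gene the authors assigned to it, the class of the position (intron, exon, promoter or transcript end), the distance to a transcript start and functional terms of the gene. Promoter peaks in these lists lay within 2 kb of a transcript start. The lists held no fold enrichment, q-value, summit or read count, so no peak could be ranked by strength, and the depth of each library is unknown. Each list stems from 1 IP, with no pooling of replicates.

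The highest peak number was 437186 in the ASPM list and 159281 in the FoxM1 list, against 184037 and 64107 listed peaks. Numbers ran in genome order, and no listed peak was annotated as intergenic. Differences between peak numbers were therefore used to count listed and unlisted peaks together when peak density along the chromosomes was measured, in bins of 5 Mb with linear interpolation between listed peaks. The positions of the unlisted peaks were not analysed here. Density per chromosome was taken over chromosomes 1 to 22 and X.

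Gene coordinates came from the RefSeq gene table of GRCh38.p14, the same build. Of the gene names in the lists, 97.0% (10442) in the ASPM list and 97.1% (7599) in the FoxM1 list matched a protein-coding gene of that table on the same chromosome, by symbol or by an unambiguous synonym. The background for gene comparisons was the 19970 protein-coding genes on chromosomes 1 to 22 and X.

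No group had a replicate, so no test between conditions was made and no p-value was computed. Shares carry exact Clopper-Pearson 95% intervals that cover counting error only, since neighbouring peaks are not independent. Ratios of peak densities carry 95% intervals from Poisson resampling of the counts. The share of FoxM1 peaks with at least 1 bp in an ASPM peak was set against 100 circular shifts of the ASPM list within its chromosomes. The number of genes with a promoter peak in both lists was set against the number for independent lists. The share of 15 fixed gene lists with a promoter peak was placed among 10000 random gene lists of equal size, as a percentile that describes these libraries only. The lowest percentile a list is able to reach, that of a list without any peak, was computed after the results were seen. Functional terms of 15 to 500 genes were treated in the same way, among the genes that carry any term in the lists.

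The gene lists, the comparisons and their main settings were fixed before the data were examined. The rule for named genes took ASPM and FOXM1, the 10 genes with the strongest promoter peak per IP, the 10 strongest in both, and up to 4 members per gene list; members beyond 4 that complete a count of 5 or fewer were named after their values were seen. Not every gene taken by the rule is reported here. That rule ranked peaks by fold enrichment, q or score. With none of these in the lists, peak width took their place, a choice made after the columns of the lists were seen. Matching of random lists on promoter GC and the search for motifs need a genome sequence and were not run.

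Alternatives planned beforehand were chromosomes 1 to 22 and X only, a distance to the transcript start of at most 1 kb in place of the promoter class, an overlap of at least 50% of both peaks, centres within 200 bp, overlap without promoter peaks, the promoter class alone at the loci, and any peak assigned to a gene. Alternatives added after seeing the data were peaks of at least 300 bp, shifts of the whole ASPM list by 10 to 100 kb, which keep each peak in its region, shifts within sequence covered by coding genes, leading functional terms without olfactory receptor genes, an ASPM list thinned to the length of the FoxM1 list, matching of random lists on regional peak density (10 classes) and gene length, and changes to the window and gene length used near transcript starts. Settings on q and fold enrichment were not run. In the test of a control window near transcript starts, the prediction was rewritten after its outcome was known, to compare the rise at 5 kb with all marks from 1 to 28 kb in place of 7 to 28 kb. The predictions for copy number and the reading of the overlap shifts were likewise changed after their values were seen. Terms are carried by listed peaks only, so genes without a listed peak are missing from the term background.

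Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and list procedures were tested on simulated data. All 1000 planted overlaps among 5000 simulated peaks were recovered, all 50 planted gene lists lay in the top 2.5% of random lists, and 3% of 400 unplanted lists lay in the top or bottom 2.5%.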

Results

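The series profiled chromatin occupancy of ASPM and FoxM1 in cells given as HepG2, and its title names a reciprocal regulation of both genes. ASPM is a spindle-pole protein whose loss causes primary microcephaly, and FoxM1 is a forkhead transcription factor that drives genes of the G2 and M phases. There was 1 IP and 1 control library for each protein. All values below describe these libraries, since no group had a replicate, and intervals cover counting error only.

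The ASPM list held 184037 peaks and the FoxM1 list 64107, a ratio of 2.87. Depth is unknown for the libraries behind them, so this ratio is no measure of how many sites each protein has. Peaks were narrow in both lists, with a median width of 203 bp for ASPM and 200 bp for FoxM1. The narrowest peaks were 159 bp wide, and 36.7% of ASPM peaks (95% interval 36.5 to 36.9) and 35.1% of FoxM1 peaks (34.8 to 35.5) had exactly that width. Peaks of at least 300 bp numbered 45128 and 12692.

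The ASPM gene held peaks of both lists, and the FOXM1 gene held none in either. From 10 kb upstream of ASPM to its end (chromosome 1, gene at 197084127 to 197146669, hg38), there were 16 peaks of the ASPM list and 10 of the FoxM1 list. Of these, 15 and 9 were assigned to ASPM, and the remaining peak of each list lay in exon 11 of the neighbouring gene ZBTB41. No listed peak was a promoter peak. The listed ASPM peak nearest to the ASPM transcript start lay at 197143566 to 197143856 in exon 3, 2958 bp downstream, and the nearest FoxM1 peak at 197142461 to 197142688 in the same exon, 4095 bp downstream. By the peak numbers, 3 unlisted ASPM peaks and 0 unlisted FoxM1 peaks lay in the interval of 11.8 kb (11.3 kb for FoxM1) that spans this start, up to the ZBTB41 peak, and their positions were not analysed here. The widest ASPM peak of the gene covered 556 bp of exon 18, at 197102338 to 197102893, and the widest FoxM1 peak covered 396 bp of intron 26, at 197087911 to 197088306. No peak of the ASPM list in the gene overlapped a FoxM1 peak, although 5 of the 15 had their centre within 1 kb of the centre of one. With only peaks of at least 300 bp, 4 ASPM peaks and 1 FoxM1 peak were left at this locus.

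**Figure D1:**
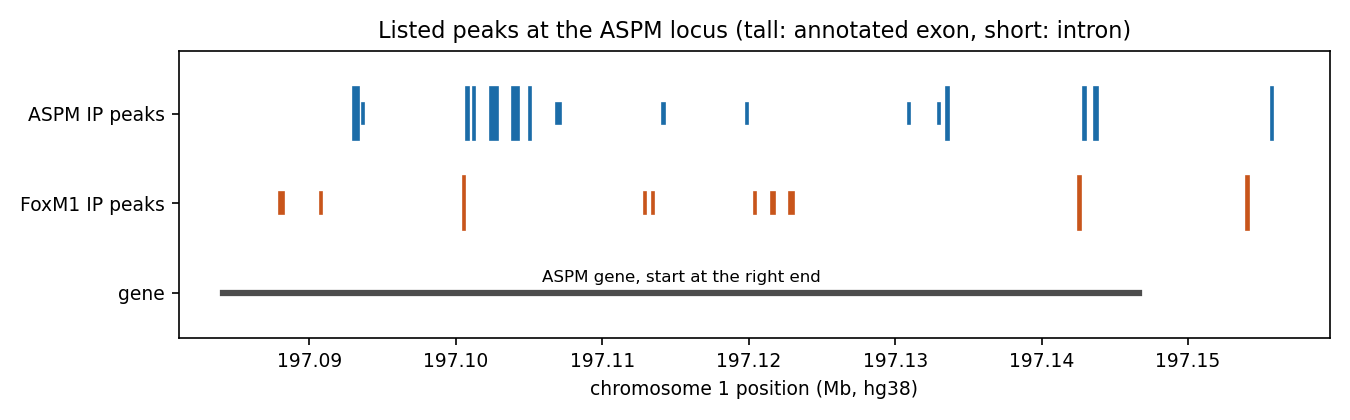
Listed peaks from 10 kb upstream of ASPM to its end, along chromosome 1 (position in Mb, hg38), with ASPM IP peaks in the upper row (16) and FoxM1 IP peaks in the row below (10), each drawn at its own width; tall boxes lie in exons and short ones in introns. The gene is the grey line, its transcript start is at the right end, and no listed peak lies within 2 kb of it.

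At FOXM1 (chromosome 12, 2857680 to 2877174), no peak was listed in either IP from the end of the gene to 10 kb upstream. The nearest listed ASPM peaks were assigned to CACNA1C, 163 kb beyond the end of the gene, and to TULP3, 21.6 kb beyond the upstream limit. In the FoxM1 list they were assigned to CACNA1C at 284 kb and PRMT8 at 499 kb. Between these neighbours the peak numbers left room for 11 unlisted ASPM peaks over 214 kb and 5 unlisted FoxM1 peaks over 812 kb, whose positions were not analysed here. The 5 Mb bin that holds FOXM1 had 110 ASPM and 33.5 FoxM1 peaks per Mb, and the bin that holds ASPM had 315 and 122. These bin values include unlisted peaks, while listed peaks at the ASPM locus came to 22.1 and 13.8 per 100 kb. Between the listed peaks on both sides of the ASPM window there were also 6 unlisted ASPM peaks over 93.8 kb. For FoxM1 there were 3 over 111 kb. With these counted, neither list was denser there than in its bin. ASPM (62543 bp) is longer than FOXM1 (19495 bp) and lies in the denser bin, so region and length alone give it more peaks. Counts of listed and unlisted peaks show no excess at ASPM over its region, and no further test of it was made. The contrast does not show binding at ASPM and its lack at FOXM1.

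The G1/S genes in the ASPM list lay in the bottom 2.5% of random lists, and the G2/M genes did not. Their shares had overlapping intervals (0 to 10.9% and 0.611 to 16.9%), so no difference between G1/S and G2/M genes is concluded. Among 40 G2/M genes, the textbook targets of FoxM1, ASPM promoter peaks were found at 2 (5.00%, 0.611 to 16.9), NEK2, a centrosomal kinase, and ECT2, a guanine exchange factor of cytokinesis. Both peaks had the minimum width of 159 bp. FoxM1 promoter peaks were found at 0 of 40. The median of random lists was 12.5% for ASPM and 5.00% for FoxM1, which placed the G2/M genes at percentiles 6.72 and 7.0. The 32 G1/S genes, textbook E2F targets, had no promoter peak in either list, percentile 0.665 for ASPM (1.07 when matched on regional density) and 10.3 for FoxM1. With any assigned ASPM peak, 14 of the 32 had one, percentile 16.7. No FoxM1 count can be lower than 0, so neither cell-cycle list was able to reach the bottom 2.5% of the FoxM1 list, and the same holds for 13 of the 14 lists other than olfactory receptors. Counting any peak assigned to the gene, 25 of the 40 G2/M genes (62.5%) had an ASPM peak and 15 (37.5%) a FoxM1 peak. Random lists matched on regional peak density and gene length had medians of 55% and 37.5%, which placed the G2/M genes at percentiles 86.6 and 51.2.

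Other lists that bear on the 2 proteins or the tissue mostly lay within the range of random lists. Of 30 primary microcephaly and spindle-pole genes, 5 had an ASPM promoter peak, namely COPB2, a coatomer subunit, KATNA1, the catalytic subunit of katanin, CEP152, a centriole duplication factor, NUP37 of the nuclear pore, and PHC1, a Polycomb protein (percentile 74.8). COPB2 and WDFY3 had a FoxM1 promoter peak (percentile 69.8). Of 30 Wnt pathway genes, ASPM peaks marked the promoter of DKK1 alone, a secreted Wnt inhibitor (3.33%, percentile 5.22), and FoxM1 peaks none. Matched on regional peak density, the Wnt list lay at percentile 2.16 for ASPM. Of 36 hepatocyte genes, 5 had an ASPM promoter peak, NR5A2, APOH, AFP, FGG and NR1H4 (percentile 60.8), and 0 had a FoxM1 promoter peak (percentile 8.51). Of 25 homologous recombination and damage-response genes, MRE11, ATR, CHEK2 and TOPBP1 had an ASPM promoter peak and none had a FoxM1 promoter peak. None of 22 p53 target genes had a promoter peak in either list, the lowest count possible (percentile 2.75 for ASPM, 1.86 when matched on regional density, and 16.7 for FoxM1). Of 26 epithelial-mesenchymal transition genes, MMP2 and SNAI2 had an ASPM promoter peak and ITGB1 and TGFBR2 a FoxM1 promoter peak. Of 22 immediate early genes, 1 had a promoter peak, ATF3, in both lists.

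Control lists gave the clearest departure. Olfactory receptor genes, which are expressed in sensory neurons of the nose, had an ASPM promoter peak at 170 of 390 (43.6%, 38.6 to 48.7) and a FoxM1 promoter peak at 101 of 390 (25.9%, 21.6 to 30.5). Both shares lay above all 10000 random lists, whose medians were 12.6% and 4.87%, and above all random lists matched on regional peak density, with medians of 15.6% and 6.15%. Widest among them were the ASPM peaks of OR1L1 (1190 bp), OR2T2 (920 bp), OR2A7 (844 bp) and OR10K2 (804 bp). These genes have close paralogs, so the reads behind a single peak are uncertain. Random lists reflect the starts of other genes, where peaks were scarce, and olfactory receptor starts were not compared with gene bodies. With any assigned peak in place of promoter peaks, the olfactory receptor genes lay at percentile 92.8 for ASPM and 24.6 for FoxM1. They lay above all random lists again once gene length and region were matched. Ribosomal protein genes lay at the other end, with an ASPM promoter peak at 3 of 60 (RPS23, RPS20 and RPS3, percentile 2.71) and a FoxM1 promoter peak at 0 of 60 (percentile 2.58). Matched on regional density, the ribosomal percentiles were 8.53 and 5.47.

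The remaining control lists also lay outside the top and bottom 2.5% of random lists. Neuronal genes had 2 of 30 in each list, with STMN2 in both and GRIA1 in the FoxM1 list (percentiles 16.9 and 69.3). Lymphoid and myeloid genes had 4 of 26 for ASPM, CD2, CD3G, PTPRC and FCGR3A, and 3 of 26 for FoxM1, GZMB, PTPRC and FCGR3A (percentiles 67.5 and 92.0). Stellate, fibroblast and endothelial genes had 5 of 21 for ASPM, LYVE1, STAB2, RGS5, COL1A2 and COL3A1, and 3 of 21 for FoxM1, LYVE1, RGS5 and ACTA2 (23.8% and 14.3%, percentiles 92.3 and 95.1). Zinc finger genes, taken by a symbol of ZNF and a number, had 56 of 477 for ASPM and 22 of 477 for FoxM1. Their percentiles were 27.9 and 41.2, with ZNF334, ZNF366 and ZNF883 in both lists. The list was meant for KRAB-type genes, but the presence of a KRAB domain was not checked. In all, 30 such percentiles were computed over 15 lists and both IPs.

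**Figure D2:**
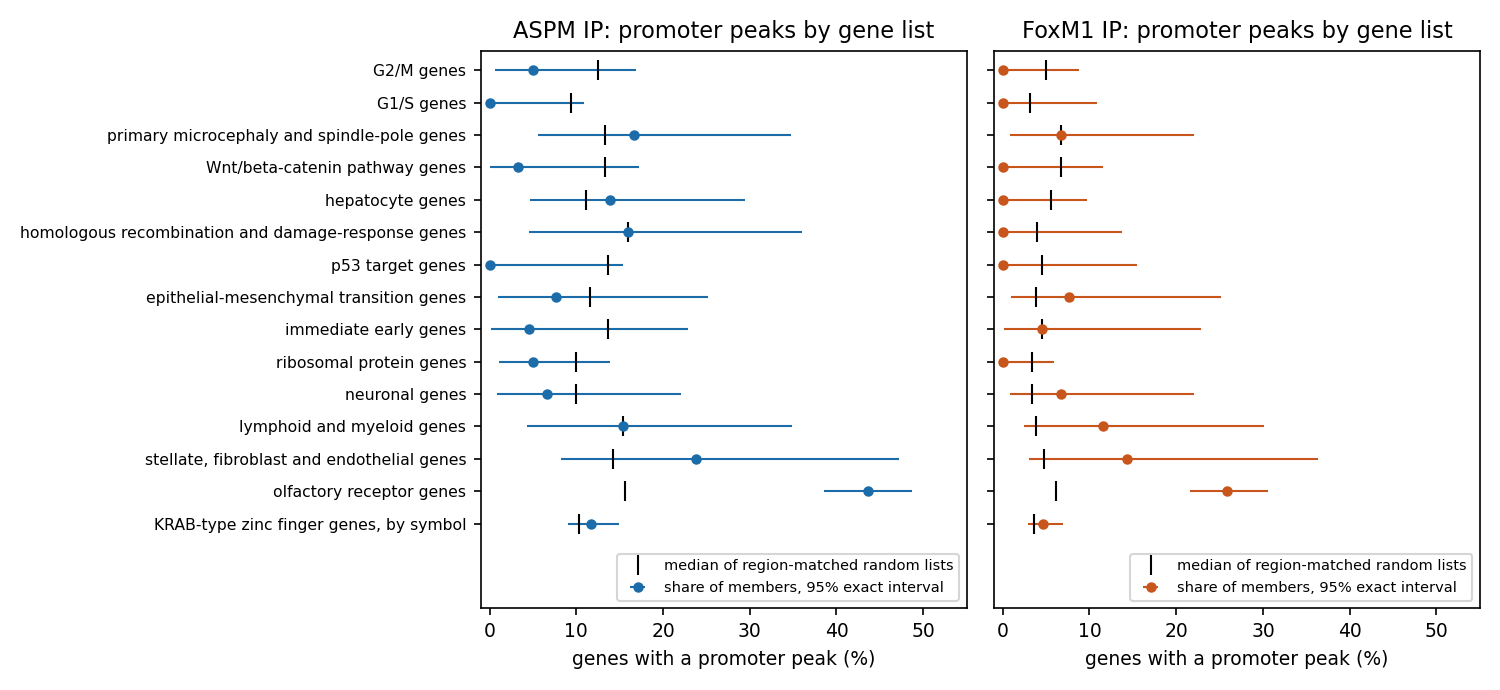
Share of each gene list with a promoter peak (x axis, percent of genes) in the ASPM IP (left) and the FoxM1 IP (right); points are shares, lines their exact 95% intervals and black ticks the median of random lists matched on regional peak density. Olfactory receptor genes stand at 43.6% and 25.9%, to the right of their ticks at 15.6% and 6.15%.

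Over all coding genes, 2527 of 19970 (12.7%) had an ASPM promoter peak and 971 (4.86%) a FoxM1 promoter peak. Both lists marked 587 genes, 60.5% of the FoxM1 set, where independent lists would share 123, a ratio of 4.78. Within classes of genes of like regional peak density 188 shared genes were expected, a ratio of 3.12. In 231 genes the promoter peaks themselves overlapped. A shared gene can have its promoter peaks at different annotated starts. The widest ones of COPB2 began at 139388325 (ASPM) and 139357250 (FoxM1) on chromosome 3. Those of RGS5 began at 163201720 (ASPM) and 163321004 (FoxM1) on chromosome 1. The widest promoter peaks of the ASPM list were those of DNAH5, an axonemal dynein (1453 bp, chromosome 5, 13942431 to 13943883), DDR2, a collagen receptor (1343 bp, chromosome 1, 162629454 to 162630796), OR1L1, the defensin genes DEFB105B (1144 bp) and DEFB103A (1126 bp), SLC13A3 (1084 bp), PPIAL4H (1066 bp), C6 (948 bp), MS4A6E (930 bp) and OR2T2. In the FoxM1 list they were HYAL4, a hyaluronidase family member (1022 bp, chromosome 7, 123828694 to 123829715), TRIM49C (985 bp), OR4F17 (742 bp), NMS (723 bp), OR2A25 (720 bp), ABCD2 (706 bp), ITPRID1 (704 bp), TAS2R39 (669 bp), UBTFL1 (663 bp) and FCGR2B (660 bp). The widest pairs in both lists belonged to TRIM49C, MRGPRX1, IL36G, DEFB118, FAM177B, OR2T29, HYAL4, UBTFL1, DEFB105B and RETREG1. Several of these genes have near-identical copies (defensins, TRIM49C, PPIAL4H, olfactory receptors), which makes their peaks uncertain.

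Peaks of both lists lay mainly inside introns and were scarce at transcript starts. Introns held 93.1% of ASPM peaks (93.0 to 93.2) and 93.3% of FoxM1 peaks (93.1 to 93.5). Exons held 4.37% and 4.19%, promoters 1.94% (1.88 to 2.01) and 1.90% (1.79 to 2.01), and transcript ends 0.592% and 0.599%. These shares are over listed peaks, which include no intergenic ones. They were not set against the shares of shuffled positions, so they show no preference for introns. In 3351 coding genes of at least 100 kb, the density of ASPM peaks within 2 kb of the start was 0.343 times (0.318 to 0.370) that found 10 to 30 kb downstream. For FoxM1 the ratio was 0.291 (0.253 to 0.332). From 2 to 5 kb downstream the ratios were 0.632 and 0.479, and from 5 to 10 kb they were 0.999 and 1.03.

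**Figure D3:**
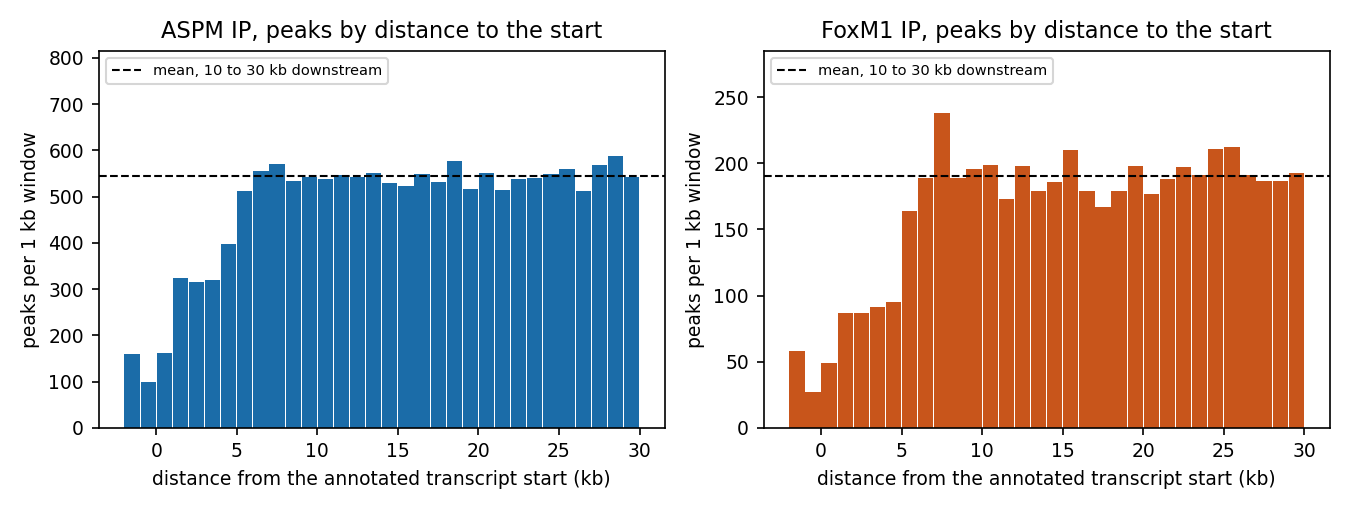
Number of listed peaks per 1 kb window (y axis) by distance from the annotated transcript start in kb (x axis, negative upstream), in 3351 coding genes of at least 100 kb, for the ASPM IP (left) and the FoxM1 IP (right). Bars are counts, the dashed line is the mean from 10 to 30 kb downstream (544 and 190 peaks per kb), and the bars near the start stay below it in both lists.

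Listed peaks of the 2 IPs overlapped more often than shifted positions, by a factor that depended on where shifted peaks could fall. Of 64107 FoxM1 peaks, 13791 shared at least 1 bp with an ASPM peak, 21.5% (21.2 to 21.8), and 7.49% of ASPM peaks shared at least 1 bp with a FoxM1 peak. Circular shifts of the ASPM list gave a mean of 3.95% of FoxM1 peaks and a range of 3.44 to 4.89%, so the observed share was 5.44 times the mean. Shifts of 10 to 100 kb, which keep each peak in its region, gave 11.3% (range 9.46 to 14.1%), and the ratio was then 1.90. Since no intergenic peak is listed, both circular shifts and shifts of 10 to 100 kb move peaks into sequence where none are listed. This lowers the shifted overlap by construction and raises both ratios. Among peaks inside coding genes, 12943 of 60280 FoxM1 peaks (21.5%) overlapped an ASPM peak. With shifts kept inside coding genes the mean was 8.50% for circular shifts (ratio 2.53) and 13.5% for shifts of 10 to 100 kb (range 12.6 to 14.6%, ratio 1.59).

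Peak density differed several-fold between chromosomes, with chromosomes 5 and 7 highest and chromosome 4 lowest in both lists. Chromosome 7 had 277 ASPM peaks per Mb and chromosome 5 had 269, which is 2.20 and 2.14 times the median chromosome. In the FoxM1 list chromosome 5 had 122 peaks per Mb and chromosome 7 had 118, 3.09 and 2.98 times the median. Chromosome 4 had 46.6 ASPM and 7.87 FoxM1 peaks. Within chromosomes the density changed in broad steps. The first 45 Mb of chromosome 5 had 448 ASPM and 253 FoxM1 peaks per Mb, whereas 95 to 170 Mb had 171 and 50.8. Chromosome 2 had 183 and 63.6 up to 120 Mb but 56.5 and 9.0 from 130 to 240 Mb. Chromosome 20 had 63.0 and 8.85 up to 25 Mb and 201 and 117 from 30 to 64 Mb. Across 599 bins of 5 Mb, densities of the 2 lists correlated with Pearson's r of 0.956 and Spearman's rho of 0.957, across bins that are not independent of one another.

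**Figure D4:**
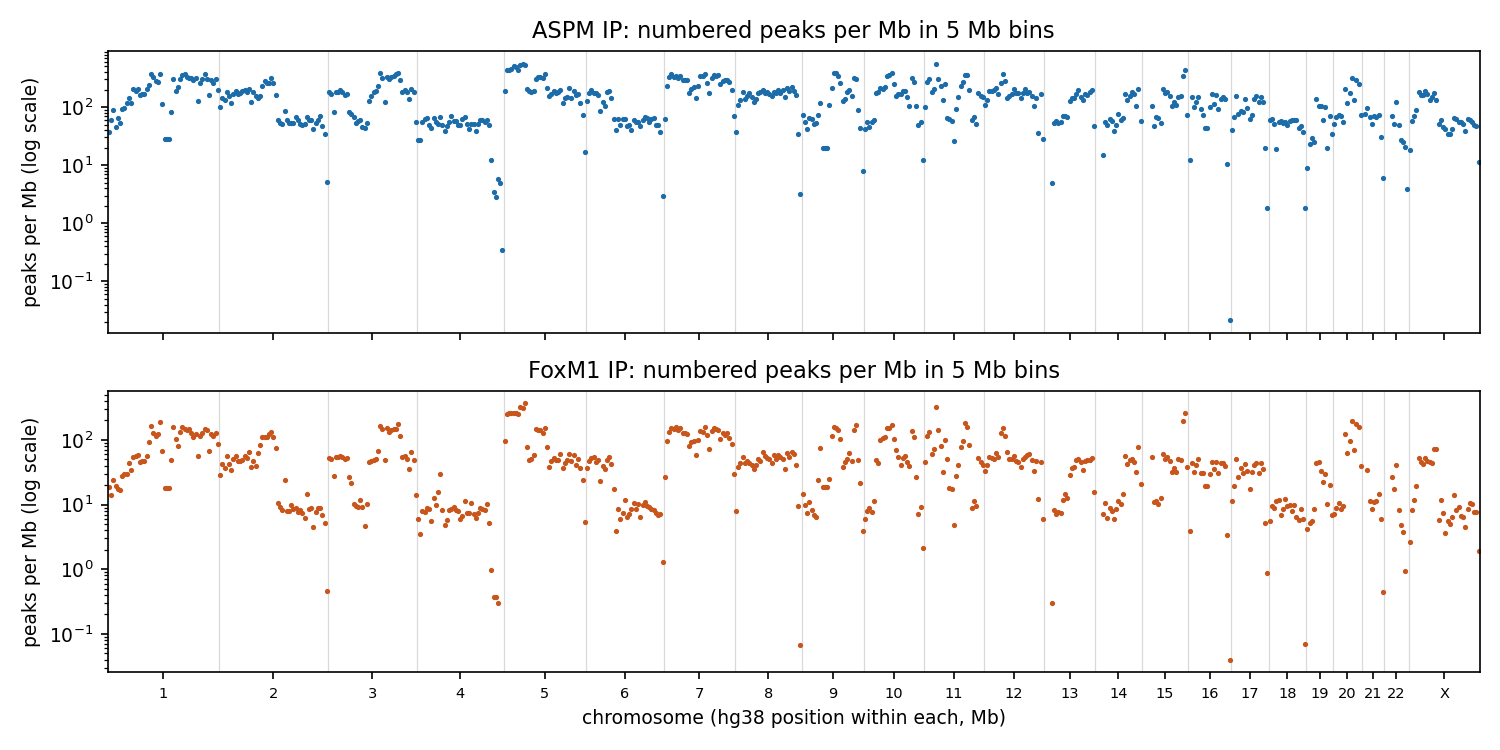
Numbered peaks per Mb (y axis, log scale) in 5 Mb bins along chromosomes 1 to 22 and X (x axis, hg38), for the ASPM IP (upper panel) and the FoxM1 IP (lower panel); each point is a bin and grey lines part the chromosomes. The first part of chromosome 5 and chromosome 7 stand high in both panels, and chromosomes 4 and 18 low.

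Functional terms came with the listed peaks, so their shares describe only genes that have a listed peak. The background was the 9035 genes with a term in either list, and a gene without a peak is missing from both term and background. This raises promoter shares, as olfactory receptor activity had an ASPM promoter peak at 166 of 228 genes (72.8%), whereas the full list of olfactory receptor genes had 170 of 390 (43.6%). No excess or lack of promoter peaks at a term is therefore concluded. Within this background, defense response had an ASPM promoter peak at 28 of its 36 genes with a listed peak (77.8%), extracellular region at 126 of 299 (42.1%), and G-protein coupled receptor activity without olfactory receptor genes at 46 of 161 (28.6%). Nuclear speck had 8 of 105 (7.62%) in the ASPM list, and chromatin binding had 1 of 103 (0.971%) in the FoxM1 list. Of 832 terms, 30 in the ASPM list and 32 in the FoxM1 list lay in the top 0.5% of random sets. In the bottom 0.5% there were 27 and 10. An even spread of percentiles would give 4.16 at each end, but terms of few genes cannot reach the bottom in the FoxM1 list. With 0 FoxM1 promoter peaks, a term of 25 genes lay at percentile 4.48 and another of 48 genes at 0.53. With random sets matched on regional density and gene length, 20 and 18 lay at the top and 15 and 4 at the bottom. The number that chance would give at the FoxM1 bottom was not computed, so these 4 terms are not compared with it. Terms share many genes and are not independent.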

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

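Settings with peaks of at least 300 bp, shifts within the region or within coding genes, thinning, matching, 1 kb windows at starts and genes of at least 50 kb were chosen after the data were seen. No alternative was labelled a reversal, but only overlap ratios, ratios of shared promoter genes and gene lists called in the main run could receive that label. Olfactory receptor genes with any FoxM1 peak fell from above all random lists to percentile 24.6, which was labelled a move. Among results other than those 28 pairs of gene list and IP named next, 31 alternatives were labelled the same, 28 moved and 1 weaker. Over the 28 pairs of gene list and IP other than olfactory receptors, 118 alternatives kept their place within or outside the top and bottom 2.5% of random lists, 18 came to lie in them and 4 no longer did. In 62 of the 118 a list without any peak would still lie above the bottom 2.5%, so these show no stability toward low shares. All 4 were G1/S genes in the ASPM list, and 2 of them lay at percentiles 16.7 with any peak and 18.8 with any peak and matching on region and length. The other 2, within 1 kb (6.79) and at 300 bp or wider (14.015), still had 0 of 32 genes, the lowest count possible, and say nothing against the main result. Peaks of at least 300 bp left 45128 ASPM and 12692 FoxM1 peaks, 4 and 1 of them at the ASPM locus, where the promoter class alone left 0 in both lists. With these wider peaks the ASPM density near starts was 0.302 of that downstream, the overlap was 14.7%, 7.69 times that after circular shifts and 2.22 times that after shifts of 10 to 100 kb, and 85 promoter genes were shared, 10.5 times the number for independent lists. Fewer peaks by construction lower the counts, and the cause of the higher ratios was not tested. A distance of at most 1 kb to the start gave promoter shares of 0.779% and 0.749%, as the window is narrower, and 197 shared promoter genes, 7.87 times the number for independent lists. Within 1 kb of starts the density ratio was 0.240 for ASPM and 0.200 for FoxM1. An overlap of at least 50% of both peaks was found for 7.36% of FoxM1 peaks, centres within 200 bp for 17.5%, and 7.497% overlapped when the ASPM list was thinned to the length of the FoxM1 list. Shifts of 10 to 100 kb brought the overlap ratio from 5.44 to 1.90, and matching on regional density brought the ratio of shared promoter genes from 4.78 to 3.12. Circular shifts within coding genes, which do not keep the region, gave an overlap ratio of 2.53, and shifts of 10 to 100 kb within coding genes gave 1.59, so both the restriction to genes and the region lower it. With any assigned peak in place of promoter peaks, olfactory receptor genes lay at percentile 92.8 for ASPM and 24.6 for FoxM1, and above all random lists once gene length and region were matched. Matching of functional terms left 15 ASPM terms in the bottom 0.5% in place of 27, and 18 FoxM1 terms in the top 0.5% in place of 32 with 4 in the bottom 0.5% in place of 10.

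All alternatives on q and fold enrichment, lists of equal length by q, motif settings and GC matching were not run, since the lists hold no such values and no genome sequence was used. No paired analysis was possible because each group holds 1 library. Depth is unknown, so a gene without a listed peak is not shown to be unbound.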

Other observations

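The tests of copy number, of the chromosome gains described for HepG2 and of a control window, the shifts inside coding genes, and the comparisons matched on region or split by regional density, were chosen after the results were seen.

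The most peaks per gene were found in long genes, and these counts are not corrected for gene length. CNTNAP2 had 733 ASPM and 280 FoxM1 peaks, DLG2 717 and 278, CTNNA3 623 and 241, and CDH12 606 and 306, while PTPRT, a receptor phosphatase, led the FoxM1 list with 310. Per 100 kb of gene, among 3351 coding genes of at least 100 kb, ALDH1A2 (102, counting interval 84.6 to 123), TMEM182 (101) and LSAMP (83.3) led the ASPM list and LGR4 (52.4, 39.6 to 68.1), DEUP1 (47.9) and ANO3 (47.8) the FoxM1 list. Of the 100 highest genes, 27 in the ASPM list and 29 in the FoxM1 list lay on chromosome 5. Peak density per gene correlated between the lists with a Spearman's rho of 0.904 across genes, which are not independent replicates. These genes were chosen by their values.

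Zinc finger genes with a symbol of ZNF and a number often held a peak outside their promoters. Any ASPM peak was found in 321 of 477 (67.3%, median of matched random lists 47.8%) and any FoxM1 peak in 219 of 477 (45.9%, matched median 29.98%). Their peak number was 1.12 and 1.11 times the number that their length and bin would give. These genes form clusters of similar sequence. In the ASPM gene, whose protein the ASPM IP targeted, 9 of 15 ASPM peaks lay in exons (60%, 32.3 to 83.7), 5 of them in exon 18, and 3 of 4028 genes with at least 10 peaks had a higher share. The median gene had 2.703%. In the FoxM1 list 2 of 9 peaks in ASPM were exonic (22.2%, 2.81 to 60.01), where 26 of 1695 genes with at least 9 peaks had a higher share and the median gene had 0%. The exon content of the gene was not taken into account. This gene was fixed beforehand, but its exon share was examined after the peaks were seen.

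Peak density moved in broad steps along the chromosomes, and the steps were shared by both lists. A steady trend of density with gene content across the genome is argued against, since Spearman's rho with coding genes per Mb was -0.0285 in the ASPM list. This single value covers all bins, including bins without coding genes whose density was interpolated. It cannot exclude a tie of density to gene content within regions. The median step between neighbouring bins was 0.231 times that between random bins in the ASPM list and 0.198 times in the FoxM1 list, which restates the broad steps and lends no support to any one source. Regional copy number of the sequenced cells therefore stays open, as does any other feature that is constant over many megabases. This ratio alone met the prediction for copy number as first written, which was changed afterwards to ask for the gained chromosomes as well. Gains of the whole chromosomes 2, 14, 16, 17 and 20 described for HepG2 are argued against as the source of the pattern, because 0 of these 5 chromosomes exceeded the median of the other autosomes in the ASPM list and 1 of 5 did in the FoxM1 list. Parts of them did exceed these medians (157.7 and 56.3 peaks per Mb), namely chromosome 20 from 30 to 64 Mb (201 and 117) and chromosome 2 up to 120 Mb (183 and 63.6), so gains of parts stay open. Whether the sequenced cells carry the described gains, and so the identity of the cell line, was not checked. Copy number was not measured, the control libraries were not analysed here, and no biological explanation was tested.

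Fewer peaks were listed near transcript starts than farther along the same genes. Both windows belong to the same genes, so regional peak density is alike for them by design. In 4 classes of genes by regional density the ratio of start to downstream density was at most 0.367 in the ASPM list. That split could not show an effect of the region and adds no evidence against it. A 10 kb control window of the peak caller raised by reads at the transcript start stays open. Density rose by 1.44 times across the 5 kb mark in the ASPM list and 1.77 times in the FoxM1 list, against at most 1.10 and 1.20 times at marks from 7 to 28 kb, where density is level. It rose more across the 1 kb mark, by 2.52 and 2.098 times. From 1 to 4 kb the density was nearly level, with 323, 315 and 319 ASPM peaks and 87, 87 and 91 FoxM1 peaks per 1 kb window. The recovery was thus not an even slope, but a recovery away from the start for another reason was not excluded. The criterion of this test was changed after its outcome was known. As first written it compared the 5 kb mark with marks from 7 to 28 kb only, and by that criterion both lists met the prediction of a control window; marks from 1 kb onward were then added, and they left it undecided. The settings of the peak caller are not given in the sources used here. GC-rich promoter sequence stays open, because ribosomal protein genes lay at percentile 8.53 of region-matched lists, neither low enough nor high enough to decide, while olfactory receptor genes, whose promoters mostly lack CpG islands, lay above all of them. A true lack of both proteins at starts was not tested.

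Overlap of the 2 lists exceeded that of shifted positions by an amount that depended on how positions were shifted. Regional peak density is argued against as the whole source, since no shift of 10 to 100 kb, which keeps the region, gave more than 67.8% of the observed overlap, over all positions, inside coding genes or in any of 3 classes of bins. The mean was 52.7% over all positions, which is low by construction because shifted peaks can fall where no peak is listed, and 62.9% inside coding genes. Coding genes too can hold sequence without listed peaks, since 248 of 3351 long genes had no assigned ASPM peak. How far this lowers the share inside coding genes was not measured. The limit of at most 50%, written beforehand for excluding this explanation, was not met; the exclusion rests on the highest shift lying below the 90% that it needs, a reading made after the values were seen. Density on a scale finer than 10 kb was not tested. In the lowest of 3 classes of bins by ASPM density 7.34% of FoxM1 peaks overlapped an ASPM peak against 2.38% after shifts over all positions, and in the highest class 25% against 13.6%, where shifted peaks can again fall outside genes. Shared sequence features, shared control reads and common binding could each add to the local part, and none of them was tested.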
